A study of Mus musculus with 69 samples.

How the data were processed

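The deposited table held 1 value per probe set and array, and the submitters' processing notes named RMA, a method that corrects background, normalizes quantiles across arrays and summarises the probes of a probe set. The values, between 1.87 and 14.34, were therefore read as deposited log2 signals, and no further normalization was applied. Differences between group means are log2 fold changes, and a difference of 1 is a doubling. The table held 17306 probe sets with 1 probe set per gene, of which 16464 carried 1 gene symbol, 842 carried none and 0 carried several. Probe sets without a symbol were counted and were not named. Genome positions were not used here.

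The labels placed the 69 arrays in 14 groups by compound, dose and day. Vehicle mice were labelled for acetaminophen only, and the description of the design gave 1 vehicle set per day, so each day's vehicle mice served as controls for all 3 compounds. The comparisons of different compounds with vehicle were therefore not independent of each other. Array titles ended in a number between 97 and 208, whose meaning the labels did not state. Of the arrays, 58 carried a number up to 190 and 11 a number from 191 to 208. The replicate numbers used here follow the order of the deposited records. No paired analysis was possible because no mouse was measured more than once.

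A mean per group was fitted for each gene over all 69 arrays with limma 3.58.1 in R 4.3.3. The spread of a gene was shared by all groups, with 55 residual degrees of freedom and 3.5 prior degrees of freedom. This takes the spread as equal in all groups, which did not hold for genes that varied widely among APAP arrays. For such genes the adjusted p values are not exact, and they are too small where the groups compared vary more than the shared spread. Each comparison was a two-sided moderated test of limma with Benjamini-Hochberg adjustment over the 17306 probe sets, and genes with an adjusted p under 0.05 were called. By chance alone, about 865 probe sets would reach an unadjusted p under 0.05 in a comparison. The dose trend was a contrast of the vehicle, low, medium and high groups that is linear in mg/kg, and its value is the fitted log2 change from vehicle to the high dose. The time difference of a compound was its effect at 2 days minus its effect at 1 day, each against the vehicle of the same day. In alternatives, dim genes are those whose highest group mean did not exceed the median over all genes of their mean signal, and array weights are estimated by limma, which gives less weight to arrays far from their group. Errors printed after a group mean are standard deviations over mice, and those of fold changes are standard errors (SE) from limma. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

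A total of 39 gene lists was fixed from general knowledge of liver, the 3 compounds and the cell types a piece of liver may hold. They covered targets of the oxidative stress regulator NRF2, antioxidant enzymes, p53 targets, targets of the amino acid stress regulator ATF4, chaperones of the endoplasmic reticulum (ER), heat shock genes, immediate early genes, acute phase proteins, the interferon response, the cell cycle, cholesterol synthesis, lipogenesis, targets of the fatty acid receptor PPAR alpha, gluconeogenesis and fasting, and glucocorticoid targets. They also covered bile acid synthesis and transport, xenobiotic cytochromes P450, heme and iron, oxidative phosphorylation, ribosomal proteins, the circadian clock, male-biased and female-biased liver genes, and coagulation and complement. Cell type lists held markers of pericentral, periportal and general hepatocytes, Kupffer cells, monocytes and macrophages, neutrophils, T and NK cells, B cells, endothelial cells, stellate cells with matrix genes, cholangiocytes, erythroid cells, platelets, pancreatic acinar cells and adipose tissue. In whole liver these markers were read as shifts of gene groups, not as cell shares, and hepatocytes also express members of several of them.

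Each list with at least 5 measured genes, which was all 39, was tested against the other genes with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. The test was repeated with a correlation estimated from the data, and with fry. For each list the members called over all genes were counted, and counts "adjusted over the list alone" used the members of that list as the family of tests.

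The model, the lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took genes with 1 symbol. In each of the 6 comparisons of a high dose with vehicle it allowed the 8 largest rises and the 8 largest falls among called genes whose treated arrays all lay on the same side of the vehicle mean. To these it added up to 4 members with the smallest adjusted p of each list called by camera. Low and medium doses allowed 4 in each direction, and trends, time differences, the vehicle comparison and comparisons of compounds 5 in each direction. A set of 22 marker genes of liver toxicity could be named anywhere, whatever its result. The genes printed are part of those the rule allows, picked with their values in view.

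Fold changes of different compounds were also correlated across genes. Because these shared vehicle arrays, the correlations were set beside 200 simulations of unchanged groups. In these, the groups and their shared control were all drawn at random from 44 arrays with their group means removed. The control was thus not the real vehicle group. The correlations were also set beside values with the vehicle arrays split in all 10 ways between the compounds. A score per array was the mean, over the 42 genes called at the medium acetaminophen dose, of the array's log2 difference from the 1 day vehicle mean, with the sign turned for genes that fell in that group.

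In a self-test, 69 arrays were simulated in each of 5 runs with the vehicle means and the fitted spread of each gene, with genes independent of each other, and known changes were added to 200 genes of the high acetaminophen group at 1 day. The procedure called 84.2% of genes changed 1.5-fold (267 of 317), 96.8% of those changed 2-fold (329 of 340) and 99.7% of those changed 4-fold (342 of 343). It called 66 of 85430 unchanged genes, or 0.0773%. A shifted list was called in 5 of 5 runs, and 0 of 200 unshifted lists were called. Each gene had the same simulated spread in all groups and no array stood apart from its group. The real APAP arrays were not like this, so these shares hold for the simulated setting only.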

Results

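Liver gene expression was measured on arrays in male C57BL/6 mice, 10 weeks old, after a single dose by oral gavage. The mice received vehicle or 1 of 3 compounds that can injure liver or lung, given at several doses. Acetaminophen (APAP), a painkiller that damages liver in overdose, was given at 168.75, 225 or 300 mg/kg. Isoniazid (INZ), a tuberculosis drug, was given at 22, 44 or 88 mg/kg, and paraquat (PQ), a herbicide that cycles electrons to oxygen, at 12.5, 25 or 50 mg/kg. The doses are called low, medium and high here. All doses were sampled after 1 day, and the high doses also after 2 days. Each of the 14 groups had 5 arrays, 1 per mouse, except PQ at the medium dose with 4, which made 69 arrays, where the description of the design counted 70. RNA came from the central part of the left lateral lobe. Vehicle groups of 5 mice served each day for all 3 compounds. The number of arrays limits the precision of every value. Array medians lay between 4.23 and 4.56 log2 units, and correlations between arrays across genes between 0.9628 and 0.9973. The lowest median belonged to APAP high dose replicate 3 at 2 days alone, and the next lowest was 4.374. The mean of that array, 5.142, was also below that of every other array. The first principal component held 43.3% of the variance and the second 6.2%. Some arrays stood apart from their groups: APAP low dose replicate 1 and PQ high dose replicate 1 at 1 day resembled the arrays of the higher APAP doses, and APAP high dose replicate 1 at 1 day lay among the vehicle arrays on the first component (-12.7 against -14.4 to -8.2) but not in every gene. All 3 were kept in the groups their labels give, and several counts are also given without one or more of them.

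The comparison of each group with the vehicle of its day asks which genes each compound changed. For APAP, limma called 0, 42 and 5207 genes at the low, medium and high doses after 1 day, and 776 genes at the high dose after 2 days. INZ had 4 called genes at the high dose after 1 day and 0 in its other groups, and PQ had 0 in all 4 groups. These zeros do not show that no gene changed, since the shared spread includes the APAP arrays. Ccl2 at the low PQ dose had SDs of 0.15 and 0.15 but an SE of 0.68. At the medium PQ dose 322 genes had an unadjusted p under 0.05, where chance gives about 865.

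**Figure D1:**
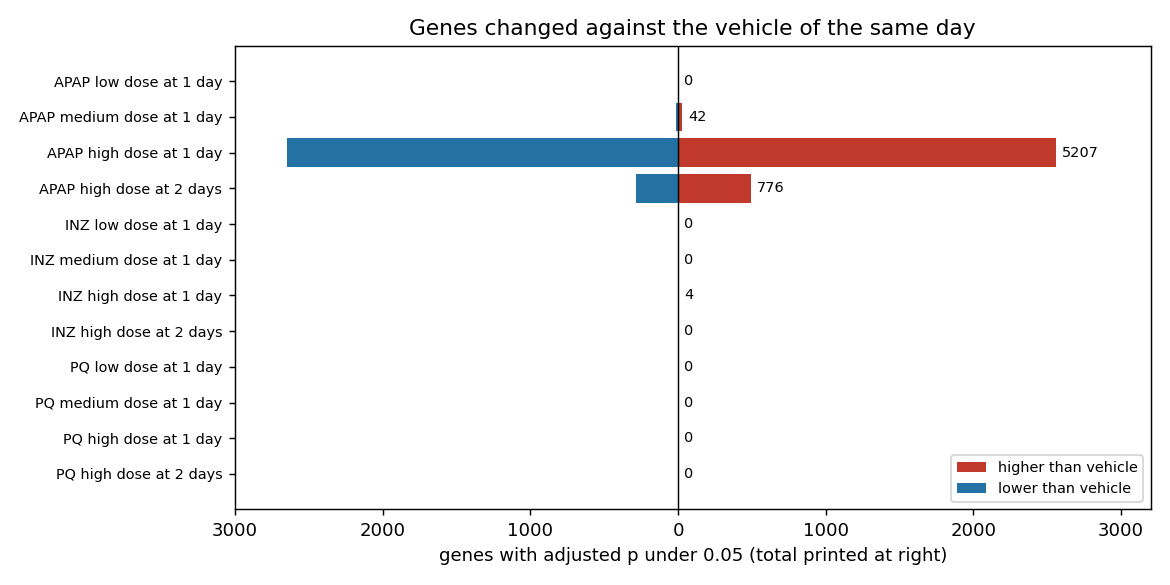
Genes called with adjusted p under 0.05 in each treated group against the vehicle of the same day; bars show the numbers of genes higher and lower than vehicle, on an axis in genes. The longest bars, 2559 higher and 2648 lower, belong to APAP at the high dose after 1 day.

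At the high dose of APAP after 1 day, 14 of 17 measured markers of monocytes and macrophages, 10 of 16 of neutrophils and 17 of 25 acute phase genes rose, and 14 of 17 genes of lipogenesis and 13 of 20 of bile acids fell. Camera called these 5 lists at its preset correlation between genes, and none of them at an estimated one (adjusted p from 0.25 to 0.30). S100a8, a calcium-binding protein of neutrophils, rose from 4.03 ± 0.34 log2 units in vehicle to 8.30 ± 2.54 (SD, n = 5 each). Chil3, a product of activated macrophages, rose from 2.98 ± 0.21 to 7.05 ± 2.87, and Psat1, an enzyme of serine synthesis, from 3.13 ± 0.19 to 6.63 ± 1.86. The vehicle means of these 3 genes lay below 4.23, the lowest median of an array, and were not shown to lie above background, so the sizes of their changes are not exact. In this comparison the same holds for Ccl2, Timp1, Ppbp, Il1rn, Atf3, Mthfd2, Cdkn1a, Hspa1a and Arntl, which are named below. Hsd3b5, a steroid dehydrogenase of male liver, fell 11.6-fold from 12.12 ± 0.14 to 8.58 ± 3.17. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 8.76-fold from 9.41 ± 0.46 to 6.28 ± 2.65. All treated arrays lay beyond every vehicle array for Psat1 (5 of 5), and 4 of 5 did for the other 4 genes. Leaving out 1 array at a time gave log2 changes of 3.79 to 5.32 for S100a8, 3.50 to 5.24 for Chil3 and 3.18 to 4.28 for Psat1. It gave -4.37 to -2.61 for Hsd3b5 and -3.98 to -2.50 for Cyp7a1. The largest change came without APAP high dose replicate 1, or replicate 4 for Hsd3b5. In limma, 5207 genes passed an adjusted p of 0.05, 2559 higher and 2648 lower, against 7139 at an unadjusted p under 0.05. Of the called genes, 1543 differed by more than 1.5-fold and 538 by more than 2-fold. The adjusted p was 0.00081 for S100a8, 0.00095 for Chil3, 0.00061 for Psat1, 0.0012 for Hsd3b5 and 0.0026 for Cyp7a1. These rest on the spread shared by all groups, which gave Hsd3b5 an SE of 0.77, where its treated arrays had an SD of 3.17. They are therefore too small for these genes. The median of all genes differed from vehicle by -0.045, and after the arrays were centred on their medians 6741 genes were called, of which 1887 were higher and 4854 lower. The fit of only these 10 arrays called 18 genes, and leaving out APAP high dose replicate 5, 3 or 2 gave 2866, 3094 or 3171 genes. Without the first replicates of the APAP and PQ high doses the count was 6903, and with array weights 8809.

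Of 17 measured markers of monocytes and macrophages, 14 rose, also 14 adjusted over the list alone, with a median log2 change of 1.60 (camera adjusted p = 1.8e-09; adjusted p = 0.25 with an estimated correlation). Among them, Lgals3, a galectin of phagocytes, rose by 3.04 log2 units (SE 0.64, adjusted p 0.00098), Ccl2, which attracts monocytes, by 3.01 (SE 0.68, adjusted p 0.0014), and Cd68 by 1.74 (SE 0.38, adjusted p 0.0011). Of 16 neutrophil markers 10 rose, 10 adjusted over the list alone, and the list was called by camera (adjusted p = 2.3e-06; adjusted p = 0.25 with an estimated correlation). S100a9, the partner of S100a8, rose by 3.61 (SE 0.77, adjusted p 0.001). Platelet markers showed 4 of 8 members higher, 4 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.25 with an estimated correlation), with Ppbp at 2.02 and Pf4 at 1.96. Of 18 stellate cell and matrix genes, 9 rose and 2 fell, and 10 and 2 did so adjusted over the list alone (camera adjusted p = 0.0016; adjusted p = 0.32 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose from 3.60 ± 0.12 to 6.60 ± 2.31 (adjusted p 0.0016), and Acta2, smooth muscle actin, by 1.86 (SE 0.44, adjusted p 0.0019). Erythroid markers were lower in 2 of 5 members, and 3 adjusted over the list alone (camera adjusted p = 0.037; adjusted p = 0.30 with an estimated correlation), a call lost without vehicle replicate 2 (0.052), after centring (0.058) and after quantile normalization (0.10). Car1 fell by 1.95 and Alas2, which makes heme in red cells, by 1.13.

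At the same dose and day, 17 of 25 acute phase genes rose, and 20 adjusted over the list alone, with a median of 0.98 (camera adjusted p = 3.7e-09; adjusted p = 0.28 with an estimated correlation). Lcn2, which binds bacterial siderophores, rose by 3.91 (SE 1.16, adjusted p 0.0093) and Il1rn, an interleukin 1 antagonist, by 1.14 (SE 0.24, adjusted p 0.00095), whereas Saa1 stood at 0.98 with adjusted p 0.24. Of 19 ER chaperones 16 rose, and 18 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 4.3e-08; adjusted p = 0.28 with an estimated correlation), among them Hspa5, the main chaperone of the ER, by 0.94 (SE 0.24, adjusted p 0.0031). Of 19 immediate early genes 10 rose, 10 adjusted over the list alone (camera adjusted p = 4.2e-05; adjusted p = 0.25 with an estimated correlation), with Ier3 at 2.53 (SE 0.44, adjusted p 0.00047) and Atf3 at 2.09 (SE 0.53, adjusted p 0.0031). ATF4 targets showed 10 of 22 higher and 1 lower, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.25 with an estimated correlation). Mthfd2, of mitochondrial folate metabolism, rose by 1.36, and Shmt2, of the same pathway, fell by 0.86. Of 24 p53 targets 9 rose and 1 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.25 with an estimated correlation), with the cell cycle inhibitor Cdkn1a at 2.89 (SE 0.66, adjusted p 0.0015).

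NRF2 targets, which answer oxidants, were higher in 10 of 26 members and lower in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.0059; adjusted p = 0.28 with an estimated correlation). Hmox1, which degrades heme, rose by 1.75 (SE 0.38, adjusted p 0.0012), Srxn1, which repairs peroxiredoxins, by 1.71 (SE 0.39, adjusted p 0.0016), and Nqo1, a quinone reductase, by 0.82 (SE 0.23, adjusted p 0.0056). Heat shock genes were higher in 7 of 13 members and lower in 1, both also adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.30 with an estimated correlation), with the chaperone Hspa1a at 2.91 (SE 0.69, adjusted p 0.0019). Ribosomal protein genes were higher in 6 of 11 members and lower in 1, the same adjusted over the list alone (camera adjusted p = 0.017; adjusted p = 0.25 with an estimated correlation), by small amounts such as 0.43 for Rps3.

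Of 17 lipogenesis genes 14 fell, and 15 adjusted over the list alone, with a median of -0.93 (camera adjusted p = 4.3e-08; adjusted p = 0.25 with an estimated correlation). Thrsp, a regulator of fat synthesis, fell by 2.64 (SE 0.52, adjusted p 0.00072), and Acacb, an acetyl-CoA carboxylase, by 1.84 (SE 0.34, adjusted p 0.00056). Of 21 pericentral hepatocyte markers, genes expressed around the central vein, 16 fell, and 18 adjusted over the list alone, with a median of -0.89 (camera adjusted p = 7.8e-07; adjusted p = 0.30 with an estimated correlation). Oat, an ornithine aminotransferase, fell by 1.45 (SE 0.31, adjusted p 0.0011) and Rhbg, an ammonium transporter, by 1.72 (SE 0.40, adjusted p 0.0017). Cyp2e1, which activates APAP, fell by 0.29 (SE 0.09, adjusted p 0.011), a call lost without APAP high dose replicate 2, where the value was -0.20 (adjusted p 0.11), or replicate 5 (-0.24, adjusted p 0.067). Bile acid genes showed 13 of 20 lower and 1 higher, 13 and 1 adjusted over the list alone (camera adjusted p = 0.00017; adjusted p = 0.30 with an estimated correlation), with the uptake transporter Slc10a1 lower by 1.12 (SE 0.21, adjusted p 0.00065) and the exporter Abcb11 by 1.35 (SE 0.28, adjusted p 0.00095). Of 23 xenobiotic P450 genes 12 fell and 1 rose, 13 and 1 adjusted over the list alone (camera adjusted p = 0.00027; adjusted p = 0.30 with an estimated correlation), with Cyp2c55 lower by 2.46 (SE 0.46, adjusted p 0.00058).

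Oxidative phosphorylation genes fell in 19 of 26 members, and 20 adjusted over the list alone, by a small median of -0.22 (camera adjusted p = 3.5e-07; adjusted p = 0.28 with an estimated correlation). Sdhb, a subunit of succinate dehydrogenase, fell by 0.43 (SE 0.08, adjusted p 0.00065). Male-biased liver genes fell in 7 of 11 members, and 8 adjusted over the list alone, with a median of -1.09 (camera adjusted p = 0.0013; adjusted p = 0.30 with an estimated correlation); Elovl3, a fatty acid elongase, fell by 3.27 (SE 0.76, adjusted p 0.0017). Circadian clock genes showed 9 of 18 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.30 with an estimated correlation), a call lost after centring (0.11). Dbp, an output regulator of the clock, fell by 1.67 (SE 0.39, adjusted p 0.0016) and Arntl, a core activator, rose by 1.41 (SE 0.37, adjusted p 0.0036). Cholesterol synthesis showed 7 of 15 members higher and 3 lower, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.30 with an estimated correlation), with the squalene epoxidase Sqle at 1.17 (SE 0.26, adjusted p 0.0012).

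**Figure D2:**
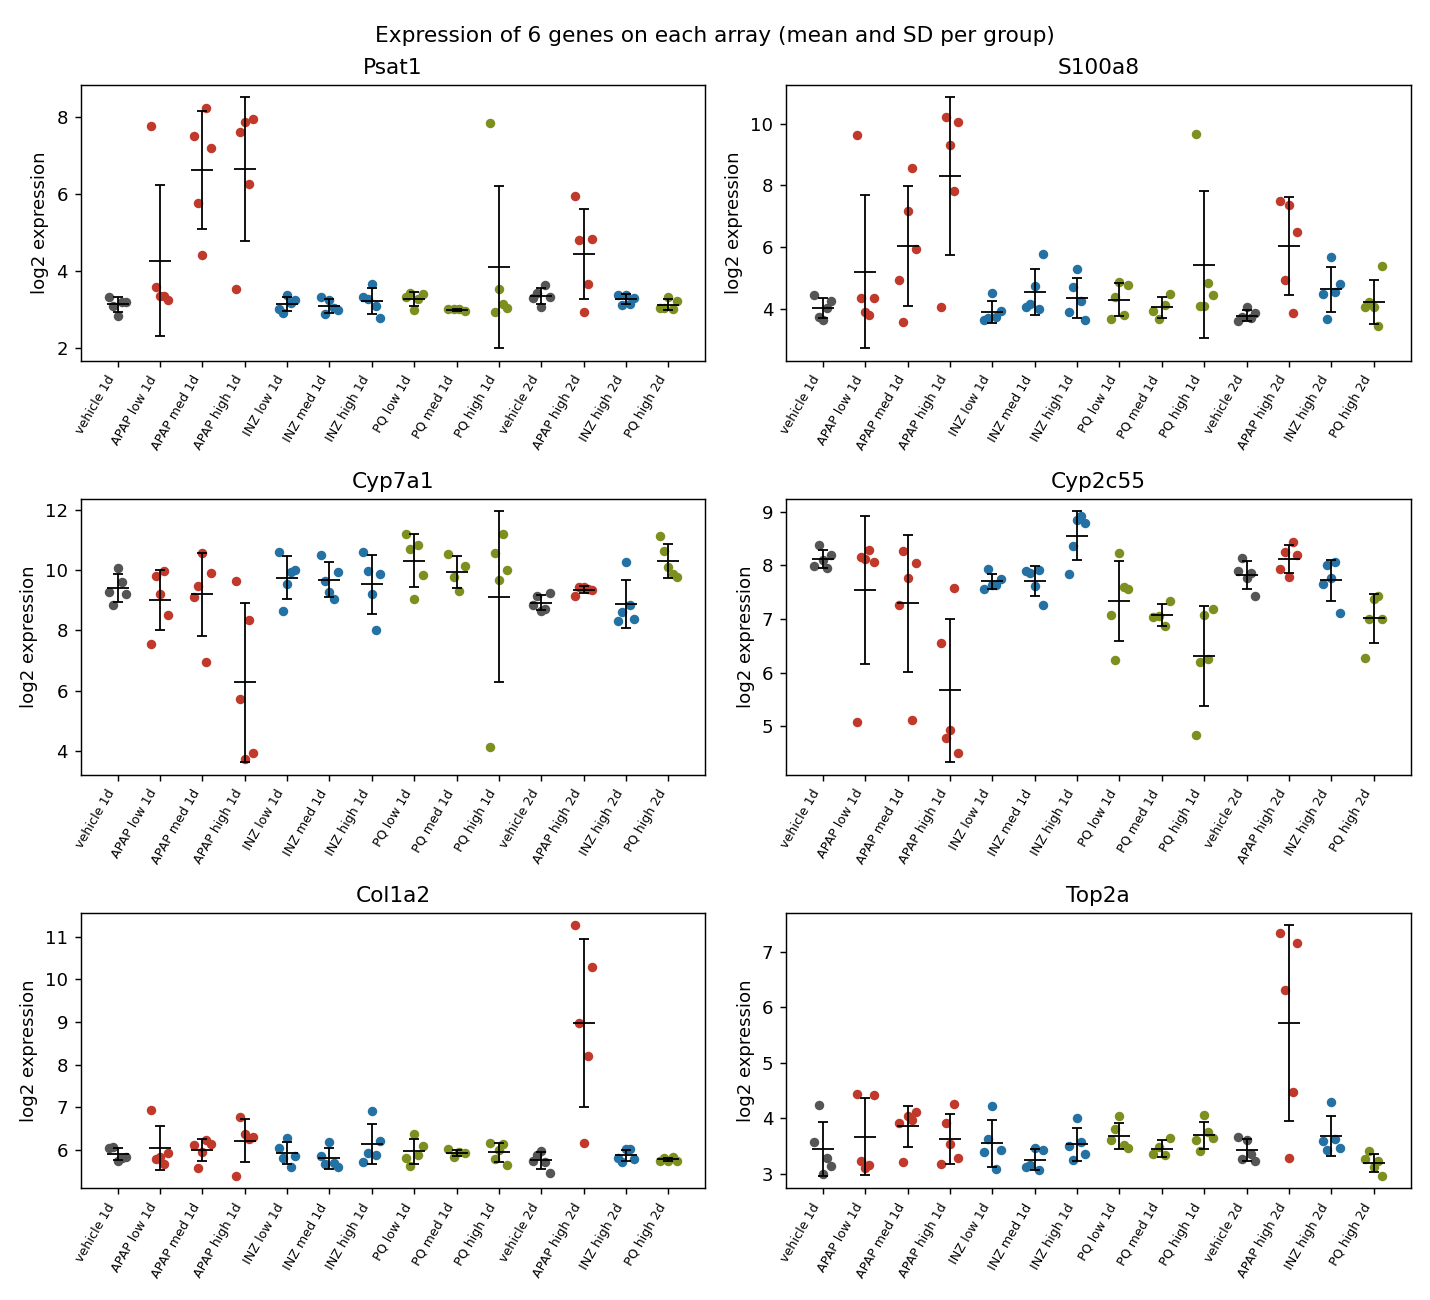
Expression in log2 units of Psat1, S100a8, Cyp7a1, Cyp2c55, Col1a2 and Top2a; each point is 1 array, and horizontal marks and bars show the mean and SD of each group. Psat1 averaged 6.63 at the APAP high dose after 1 day against 3.13 in vehicle, and Col1a2 averaged 8.98 at 2 days against 5.76.

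At 2 days after the high dose of APAP, genes of cell division and collagens stood above the vehicle of that day. So did macrophage markers, though their list call was lost at an estimated correlation. Col1a2, a chain of type I collagen, rose 9.37-fold, from 5.76 ± 0.20 to 8.98 ± 1.97 (SD, n = 5 each), with 5 of 5 treated arrays above every vehicle array. Its log2 change of 3.23 was 2.66 without APAP high dose replicate 1 and 3.93 without replicate 3 at 2 days. Top2a, a topoisomerase of dividing cells, rose from 3.42 ± 0.20 to 5.71 ± 1.77, and Kif20a, a mitotic kinesin, from 3.09 ± 0.10 to 5.30 ± 1.01. In limma 776 genes were called, 494 higher and 282 lower, with 3234 at an unadjusted p under 0.05, and 318 of the called genes differed by more than 1.5-fold. The log2 change of Top2a was 2.29, and 1.88 to 2.90 without 1 array, with 4 of 5 arrays above every vehicle array. For Top2a and Kif20a, and for Ccnb2, Col1a1, Gpnmb, Trem2 and S100a8 at this day, the vehicle mean lay below 4.23, so the sizes of these changes are not exact. The adjusted p was 3.5e-08 for Col1a2, 3.6e-05 for Top2a and 3.4e-07 for Kif20a. These rest on the spread shared by all groups, which gave Col1a2 an SE of 0.37, where its treated arrays had an SD of 1.97. They are therefore too small for these genes. The count, rounded to 2 digits where written with an exponent, was 2.0e2 and 326 without APAP high dose replicates 1 and 5 at 2 days, and 473, 490 and 482 without vehicle replicates 3, 4 and 5. It was 28 in the fit of only these 10 arrays, 345 in arrays numbered up to 190 and 1017 without the first replicates of the APAP and PQ high doses at 1 day. It was 1584 with array weights and 1402 with the vehicles of both days.

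Of 34 cell cycle genes 24 rose at 2 days, and 27 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 4e-42; adjusted p = 0.0069 with an estimated correlation). The mitotic cyclin Ccnb2 rose by 2.68 (SE 0.48, adjusted p 0.00018) and Cdc20, which starts anaphase, by 2.62 (SE 0.43, adjusted p 5.3e-05). Of 18 stellate cell and matrix genes 10 rose, and 13 adjusted over the list alone, with a median of 0.94 (camera adjusted p = 3.4e-21; adjusted p = 0.0069 with an estimated correlation), among them Col3a1 by 1.98 (SE 0.32, adjusted p 4.8e-05) and Col1a1 by 1.71 (SE 0.21, adjusted p 2e-07). Monocyte and macrophage markers rose in 8 of 17 members, and 12 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 5.7e-18; adjusted p = 0.074 with an estimated correlation). Gpnmb, a glycoprotein of phagocytes, rose by 2.46 (SE 0.41, adjusted p 5.8e-05), Trem2, a macrophage receptor, by 1.73 (SE 0.27, adjusted p 2.3e-05), and the lysozyme Lyz2 by 1.70 (SE 0.30, adjusted p 0.00017). Kupffer cell markers rose in 2 of 13 members, and 6 adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.37 with an estimated correlation). Endothelial markers rose in 1 of 18 members, Stab1 by 0.56, and 2 adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.074 with an estimated correlation).

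At 2 days PPAR alpha targets fell in 1 of 22 members, Acot1, a thioesterase of fatty acids, by 1.47 (SE 0.43, adjusted p 0.032), with 7 lower and 1 higher adjusted over the list alone. The call of Acot1 was lost without APAP high dose replicate 1 or 5 or vehicle replicate 3, 4 or 5 at 2 days, with adjusted p from 0.059 to 0.16. The list was called downward (camera adjusted p = 0.0024, and 0.56 with an estimated correlation), and the call was lost with the vehicles of both days as controls (0.58). This list was itself higher in the vehicle of 2 days than in that of 1 day. For the list, a shift of those vehicle arrays cannot be told apart from an effect of APAP. Oxidative phosphorylation genes fell in 2 of 26 members, and 4 adjusted over the list alone (camera adjusted p = 0.00026; adjusted p = 0.63 with an estimated correlation). Several genes that changed at 1 day did not pass the test at 2 days: Cyp7a1 stood at 0.43 (adjusted p 0.81), Hmox1 at 0.77 (0.26), S100a8 at 2.24 (0.13) and Lcn2 at 3.64 (0.057), which passed without APAP high dose replicate 2 or 4 (0.042 and 0.039). Acute phase genes were higher in 2 of 25 members, and 5 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 1.1e-06, and 0.56 with an estimated correlation). Camera also called the neutrophil, platelet and p53 target lists at its preset correlation. The platelet marker Pf4 rose by 2.52 (SE 0.49, adjusted p 0.00072), whereas the p53 target Sesn1 did not pass (0.25, adjusted p 0.068).

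The difference between the 2 days for APAP was tested directly. Cell cycle genes had a higher effect at 2 days than at 1 day in 17 of 34 members, and 20 adjusted over the list alone, with a median difference of 1.05 (camera adjusted p = 1.6e-16; adjusted p = 0.42 with an estimated correlation). Ccnb2, with vehicle means below 4.23, differed by 3.12 (SE 0.67, adjusted p 0.0082), Col1a2 by 2.91 (SE 0.53, adjusted p 0.0014) and Cyp2c55 by 2.76 (SE 0.65, adjusted p 0.014). Cyp7a1 differed by 3.56, with adjusted p 0.056, and passed without APAP high dose replicate 1 or 4 at 1 day (0.0051 and 0.015). Hmox1 differed by -0.97 (adjusted p 0.29) and Lcn2 by -0.27 (adjusted p 0.95), so no difference between the days was shown for these. Ier3 had a lower effect at 2 days, by -2.51 (SE 0.62, adjusted p 0.019), a call lost without APAP high dose replicate 2, 3 or 5 at 1 day (0.05, 0.069 and 0.075). ER chaperones differed downward with a median of -0.77, with 1 of 19 members called and 17 adjusted over the list alone (camera adjusted p = 2.4e-08; adjusted p = 0.42 with an estimated correlation). Limma called 487 genes, 288 of them with a lower effect at 2 days, and 3728 at an unadjusted p under 0.05. After centring, the larger part had a higher effect at 2 days, 235 of 430 genes. With the title number as covariate 223 genes were called, and 11 in the fit of only the groups compared. Without dim genes 747 were called, in arrays numbered up to 190, 3400, and with array weights 5025. The count was 2509 and 1724 without APAP high dose replicates 1 and 4 at 1 day, and 3052 without the first replicates of the APAP and PQ high doses at 1 day. It lay between 1.2e2 and 323 without APAP high dose replicate 2, 3 or 5 at 1 day or 1 or 5 at 2 days, vehicle replicate 1, 2, 3 or 4 at 1 day or vehicle replicate 3, 4 or 5 at 2 days.

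At the medium dose of APAP after 1 day, Psat1 and 3 of 26 NRF2 targets rose. Psat1 rose to 6.62 ± 1.53 from 3.13 ± 0.19, in 5 of 5 arrays (SD, n = 5 each). Its log2 change was 3.49, and 3.08 to 4.04 without 1 array, and its size is not exact, since this vehicle mean was not shown to lie above background. Abcc4, an efflux transporter, rose from 4.88 ± 0.17 to 6.91 ± 1.03, and Nqo1 from 5.91 ± 0.12 to 7.27 ± 0.68. In limma 42 genes were called, 30 higher and 12 lower, with 3187 at an unadjusted p under 0.05, and the fit of only these 10 arrays called 2. The adjusted p was 0.0051 for Psat1, 0.0039 for Abcc4 and 0.0014 for Nqo1, and Psat1 was lost without APAP medium dose replicate 4 (0.056). NRF2 targets rose in 3 of 26 members, and 13 higher and 1 lower adjusted over the list alone, with a median of 0.23 (camera adjusted p = 2.7e-09; adjusted p = 0.018 with an estimated correlation). Acute phase genes had a median of 0.46, with 0 of 25 members called and 13 adjusted over the list alone (camera adjusted p = 5e-11; adjusted p = 0.29 with an estimated correlation). Monocyte and macrophage markers had a median of 0.84, with 0 of 17 called and 7 adjusted over the list alone (camera adjusted p = 5.4e-07; adjusted p = 0.41 with an estimated correlation). Spsb4 fell by 0.66 (SE 0.14, adjusted p 0.019), a call lost without APAP medium dose replicate 4 or 5 or vehicle replicate 2 (0.078, 0.079 and 0.076). The count was 9 and 11 without APAP medium dose replicates 4 and 5, 21, 21 and 23 without vehicle replicates 2, 4 and 5, and 1.6e2 and 90 without APAP medium dose replicates 2 and 3, and after centring 46 genes were called, 19 higher and 27 lower. It was 409 without the first replicates of the APAP and PQ high doses, 418 with array weights, 332 with the vehicles of both days, 80 without dim genes and 1733 in arrays numbered up to 190.

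At the low dose of APAP limma called 0 genes, with 1105 at an unadjusted p under 0.05 and a smallest adjusted p of 0.534. NRF2 targets had a median of 0.20 and were called as a list upward, with 0 members called, also adjusted over the list alone (camera adjusted p = 0.00047; adjusted p = 0.28 with an estimated correlation). Nqo1 stood at 0.41 (adjusted p 0.76) and Hmox1 at 0.44 (0.8), which became -0.02 without APAP low dose replicate 1. The linear trend over the 4 dose levels of APAP at 1 day was called in 5076 genes, 2519 upward and 2557 downward, with 7058 at an unadjusted p under 0.05. Psat1 had a fitted change of 3.80 from vehicle to the high dose (SE 0.63, adjusted p 0.00035), S100a8 of 3.93 (SE 0.83, adjusted p 0.0013), Hsd3b5 of -3.28 (SE 0.74, adjusted p 0.0019) and Ces2b, a carboxylesterase, of -2.79 (SE 0.57, adjusted p 0.0012). For Psat1, S100a8 and Ces2b these sizes are not exact, with a mean below 4.23 in the vehicle or, for Ces2b, in the high dose group. After centring 6615 genes had a trend, 1801 upward and 4814 downward. In the fit of only these 4 groups 2.0e2 genes had a trend, and the count was 3168 without APAP high dose replicate 5 and 8511 with array weights.

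At the high dose of INZ after 1 day, 3 named genes fell. Pfkfb3, a regulator of glycolysis, fell from 6.06 ± 0.24 to 5.21 ± 0.19 (SD, n = 5 each), Lig4, a DNA ligase of double-strand break repair, from 6.21 ± 0.19 to 5.52 ± 0.18, and Tsc22d2 from 7.09 ± 0.16 to 6.48 ± 0.18, each with 5 of 5 arrays below every vehicle array. Limma called 4 genes, 1 higher and 3 lower, with 831 at an unadjusted p under 0.05, and the adjusted p of the 3 genes was 0.034. The fit of only these 10 arrays called 0 genes, and so did leaving out INZ high dose replicate 2 or 3 or vehicle replicate 2, 3, 4 or 5, with adjusted p of the 3 genes up to 0.26. Without INZ high dose replicate 4 or 5, and after centring, 2 genes were called, with array weights 10 and with the vehicles of both days 11. Cyp2b10, a P450 induced by activators of the receptor CAR, stood at 1.31 from a vehicle mean of 4.22 (SE 0.37, adjusted p 0.58), and at adjusted p 0.02 with the vehicles of both days as controls. Its size is not exact, since that mean lay below 4.23. Cholesterol synthesis genes had a median of 0.25, with 0 of 15 called and 3 adjusted over the list alone (camera adjusted p = 2.9e-06; adjusted p = 0.34 with an estimated correlation).

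The other INZ groups gave 0 calls in limma, with 929, 478 and 816 genes at an unadjusted p under 0.05 for the low dose, the medium dose and 2 days. With array weights these gave 15, 4 and 1, and the low dose gave 4 with the vehicles of both days. Cholesterol synthesis was called upward as a list at the low dose with a median of 0.36, 0 members called and 6 adjusted over the list alone (camera adjusted p = 1.2e-08; adjusted p = 0.23 with an estimated correlation). At 2 days its median was 0.32 with 0 members called, also adjusted over the list alone (camera adjusted p = 3.2e-05; adjusted p = 0.67 with an estimated correlation). PPAR alpha targets were called downward at 2 days with a median of -0.16 and 22 of 22 members below 0 (camera adjusted p = 1e-08; adjusted p = 0.36 with an estimated correlation), a call lost with the vehicles of both days (0.054). The PPAR alpha list was itself higher in the vehicle of 2 days than in that of 1 day, so a shift of those vehicle arrays cannot be told apart from an effect of INZ. The linear trend of INZ was called in 1 gene, Lig4, at -0.70 (SE 0.13, adjusted p 0.021), with 795 at an unadjusted p under 0.05. Chance was not excluded for that count, which 8 of 100 splits of the arrays reached. It was 0 in the fit of only these 4 groups, 2 with the batch as a term or in arrays numbered up to 190, and 5 with array weights. Lig4 lost that call without INZ high dose replicate 2, 3 or 4 or vehicle replicate 2, 4 or 5, with adjusted p from 0.056 to 0.21. The difference between the 2 days gave 0 genes in limma, with 881 at an unadjusted p under 0.05.

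At the high dose of PQ after 1 day, genes of fat synthesis lay below vehicle as a group and genes of cholesterol synthesis above it, with 0 single genes called in limma. Camera called both lists at its preset correlation between genes and not at an estimated one (adjusted p = 0.28 for each). Acaca, the acetyl-CoA carboxylase of fat synthesis, was at 7.42 ± 0.28 against 8.25 ± 0.12 in vehicle (SD, n = 5 each), with 5 of 5 arrays below every vehicle array (difference -0.84, SE 0.20, adjusted p 0.43). Scd1, a fatty acid desaturase, was at 11.35 ± 0.55 against 12.31 ± 0.21 (adjusted p 0.52), and Fdft1, squalene synthase, at 10.33 ± 0.35 against 9.79 ± 0.13 (adjusted p 0.59). Cyp2c55 was at 6.31 ± 0.94 against 8.12 ± 0.17 (adjusted p 0.43). The lipogenesis list had a median of -0.55, with 0 of 17 members called and 9 lower adjusted over the list alone (camera adjusted p = 6.7e-12; adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis had a median of 0.31, with 0 of 15 called and 6 higher adjusted over the list alone (camera adjusted p = 3.1e-07, and 0.28 with an estimated correlation). For cholesterol synthesis, INZ showed much the same against the same vehicle arrays, with Fdft1 higher by 0.51 at its high dose and by 0.53 with PQ. The INZ median of this list was larger at the low dose than at the high dose. A shift of the vehicle arrays cannot be told apart here from an effect of either compound. Acute phase genes had a median of 0.31, with 0 members called, also adjusted over the list alone (camera adjusted p = 6.3e-08; adjusted p = 0.58 with an estimated correlation); without PQ high dose replicate 1 that adjusted p was 0.057. Monocyte and macrophage markers had a median of 0.52, with 0 of 17 called, also adjusted over the list alone (camera adjusted p = 0.00028; adjusted p = 0.60 with an estimated correlation), and neutrophil markers a median of 0.16 (camera adjusted p = 0.022; adjusted p = 0.60 with an estimated correlation). S100a8 was at 9.67 in PQ high dose replicate 1 and at 4.11 to 4.85 in the other arrays (difference 1.41, adjusted p 0.79). Without that array the adjusted p was 0.61 for monocytes and macrophages and 0.84 for neutrophils. Of 14 lists called by camera, 4 were still called at the preset correlation without it: lipogenesis (1e-09), cholesterol synthesis (8.1e-05), Kupffer cell markers (0.0029) and endothelial markers (0.0097). With all arrays the latter had medians of 0.19 and 0.05, 0 of 13 and 0 of 18 members called, and adjusted p of 0.62 and 0.58 with an estimated correlation. None of the 14 lists was called in that test. At an unadjusted p under 0.05 there were 1082 genes, and the smallest adjusted p was 0.427. With array weights 5 genes were called.

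After 2 days at the high dose of PQ, cholesterol synthesis genes had a median of 0.41 with 15 of 15 members above vehicle, 0 called and 7 adjusted over the list alone (camera adjusted p = 2.8e-12, and 0.048 with an estimated correlation). The list was also called upward with INZ at 2 days, against the same vehicle arrays. A shift of those arrays cannot be told apart here from an effect of either compound. Pmvk, a kinase of the mevalonate pathway, was at 9.10 ± 0.17 against 8.57 ± 0.22 (SD, n = 5 each; adjusted p 0.96). PPAR alpha targets had a median of -0.21 with 22 of 22 members below vehicle (camera adjusted p = 1.6e-08; adjusted p = 0.22 with an estimated correlation), a call lost with the vehicles of both days (0.29). For PPAR alpha targets too, a shift of the vehicle arrays cannot be told apart from an effect of PQ, since the list was higher in the vehicle of 2 days than in the other vehicle group. Limma called 0 genes at 2 days and at the low and medium doses, with 628, 540 and 322 at an unadjusted p under 0.05. The trend and the difference between days also gave 0 genes, with 927 and 701 at an unadjusted p under 0.05. Lipogenesis was called downward as a list in the trend, with a median of -0.52, 0 members called and 9 adjusted over the list alone (camera adjusted p = 7e-15; adjusted p = 0.25 with an estimated correlation).

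**Figure D3:**
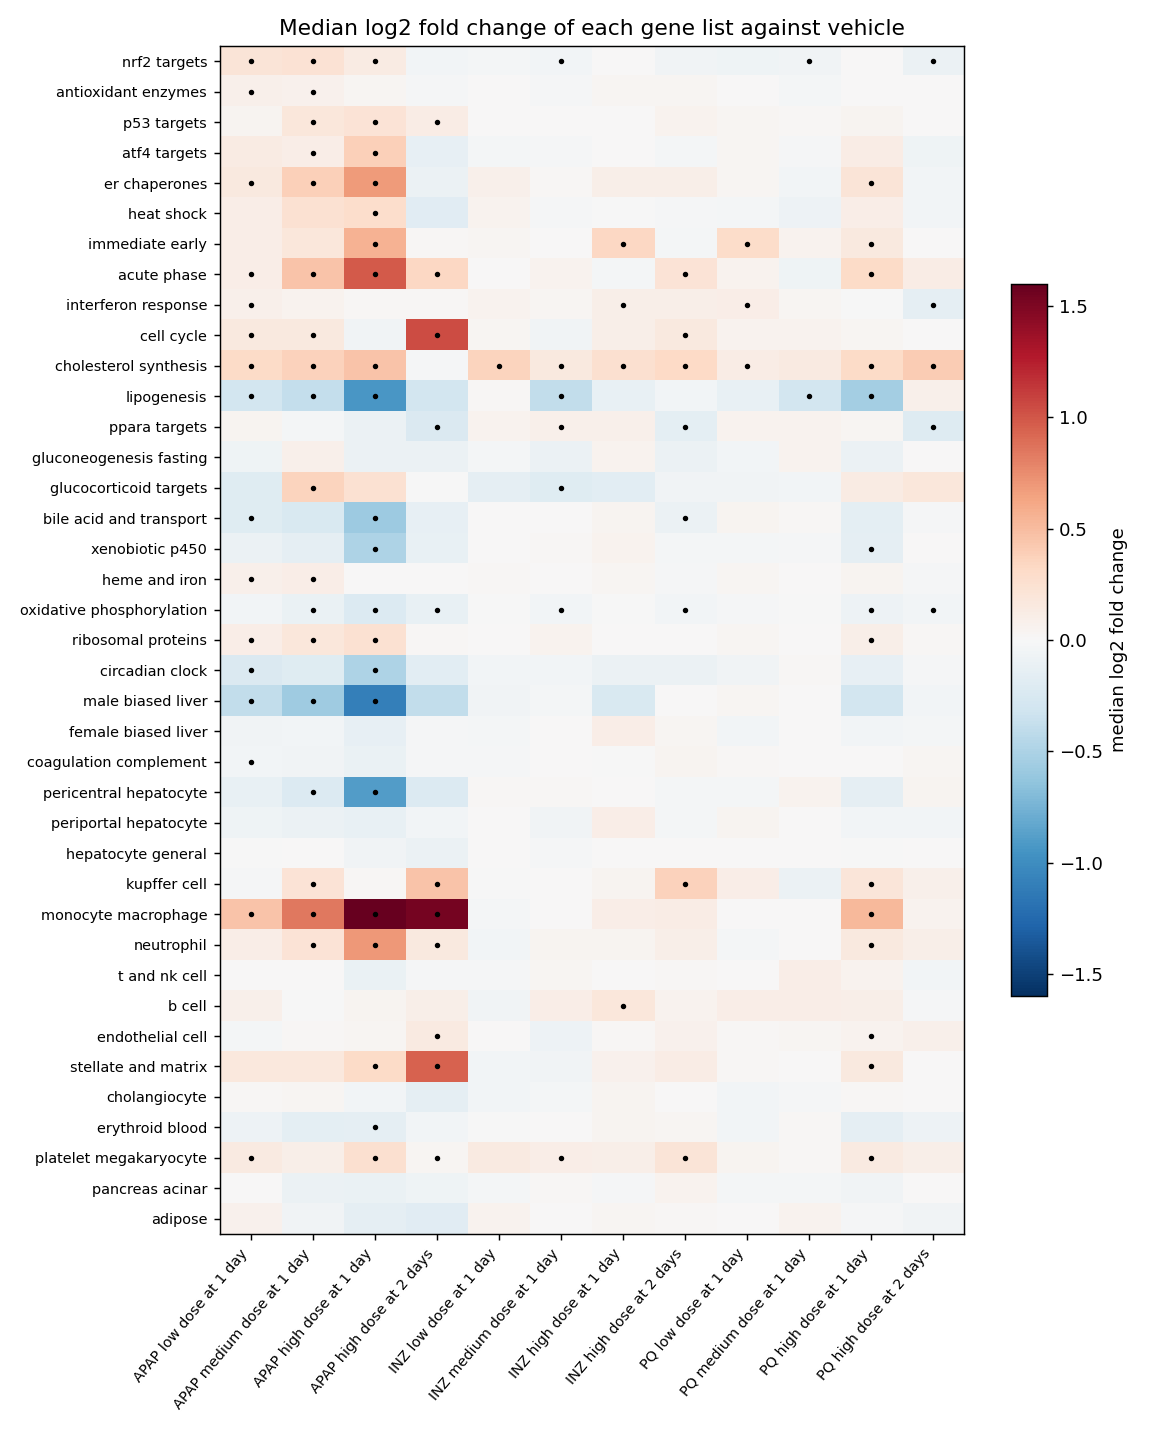
Median log2 fold change of the measured genes of each list (vertical axis) in each treated group against the vehicle of the same day (horizontal axis), in color, with dots where camera gave an adjusted p under 0.05. The monocyte and macrophage list had the median 1.60 at the APAP high dose after 1 day and 1.53 after 2 days.

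The compounds were compared at their high doses after 1 day, which differ in mg/kg. Against PQ, APAP gave higher expression of monocyte and macrophage markers, with a median difference of 1.03, 0 of 17 called and 11 adjusted over the list alone (camera adjusted p = 9.4e-09; adjusted p = 0.29 with an estimated correlation). Pericentral hepatocyte markers were lower with APAP than with PQ, with a median of -0.51, 0 of 21 called and 14 adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.29 with an estimated correlation). Lmcd1, at 3.47 with PQ and so without an exact size, was higher with APAP by 1.81 (SE 0.40, adjusted p 0.048), and Nmrk1, a kinase of nicotinamide riboside, lower by 1.58 (SE 0.39, adjusted p 0.049), and both calls were lost without APAP high dose replicate 2, 3 or 5 or PQ high dose replicate 2, 3, 4 or 5 (adjusted p from 0.13 to 0.30). Cyp7a1 differed by -2.84 (adjusted p 0.05) and Cdkn1a by 2.17 (adjusted p 0.056), and both passed without PQ high dose replicate 1 or APAP high dose replicate 1 or 4. Limma called 67 genes, 41 higher and 26 lower, with 4285 at an unadjusted p under 0.05. The count was 4449, 3965 and 2662 without PQ high dose replicate 1, APAP high dose replicate 1 and APAP high dose replicate 4, and 0 or 1 without any single one of the others. Without both APAP and PQ high dose replicate 1 it was 5990, in arrays numbered up to 190, 6210, and with array weights 7509. It was 0 in the fit of only these 10 arrays, 2 with the title number as covariate, 279 after quantile normalization, 1.8e2 after centring, 401 with the batch as a term and 1123 without dim genes. Chance was not excluded for the count of 67, which 17 of 100 splits of the arrays reached.

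Between APAP and INZ limma called 4279 genes, 2212 higher and 2067 lower with APAP, with 6304 at an unadjusted p under 0.05. Chance was not excluded for this count, which 5 of 100 splits of the arrays reached. The split with the most genes moved APAP high dose replicate 1, which lacks the response of its group. The splits therefore do not measure chance alone and do not decide this. Chil3 was higher by 4.11 (SE 0.85, adjusted p 0.00081) and Psat1 by 3.41 (adjusted p 0.00065), whereas Etnppl, an enzyme of phosphoethanolamine breakdown, was lower by 3.07 (SE 0.59, adjusted p 0.00065) and Cyp2b10 by 1.87 (SE 0.37, adjusted p 0.00075). For Chil3, Psat1 and Cyp2b10 here, and for Cyp2b10 between PQ and INZ below, the lower group mean lay below 4.23, so these sizes are not exact. The fit of only these 10 arrays called 0 genes, and the count was 2185, 2317 and 2446 without APAP high dose replicates 5, 3 and 2, and 7914 with array weights. PQ against INZ gave 5 genes, 1 higher and 4 lower, with 1051 at an unadjusted p under 0.05. Cyp2c55 was lower with PQ by 2.25 (SE 0.46, adjusted p 0.031), Cyp2b10 by 1.91 (SE 0.37, adjusted p 0.022), Cyp3a44 by 0.98 (SE 0.19, adjusted p 0.022) and Mterf2 by 0.81 (SE 0.17, adjusted p 0.031), and Baz1a, a chromatin remodeling subunit, was higher by 0.52 (SE 0.10, adjusted p 0.022). All 5 calls ended without PQ high dose replicate 1 or 2 or INZ high dose replicate 2, 3, 4 or 5, where only the last gave any gene, 1 that was not among the 5. Without PQ high dose replicate 5, 3 of the 5 were called. Arrays numbered up to 190 gave 3 genes, array weights 9 and the fit of only these 10 arrays 0.

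Across genes, which are not independent replicates, the log2 fold changes of APAP and PQ at 1 day correlated with r = 0.82, those of INZ and PQ with r = 0.43 and those of APAP and INZ with r = 0.29. A shared control group alone gave a mean r of 0.50 in simulations, and most lay between 0.28 and 0.69. The simulated groups held no effect, and an effect of 1 compound alone lowers r, so the r of pairs with APAP cannot be judged by this. The covariance, which is not divided by the spreads, was 0.054 for APAP and PQ, 0.015 for APAP and INZ and 0.0091 for INZ and PQ. Most simulations gave 0.0029 to 0.011. With the vehicle arrays split between the compounds, r was 0.69 for APAP and PQ, 0.16 for INZ and PQ and 0.17 for APAP and INZ. The mean covariances over these splits were 0.049, 0.0042 and 0.0097 in the same order. Without the first replicates of the APAP and PQ high dose groups, r for APAP and PQ was 0.23 and their covariance 0.013. With the vehicle arrays also split, that covariance was 0.0086. At 2 days r was 0.44 for APAP and INZ, 0.31 for APAP and PQ and 0.38 for INZ and PQ, and 0.28, 0.16 and 0.10 with the vehicle arrays split. APAP and INZ at 1 day shared 0 called genes in the same direction, with 0.61 expected for independent lists, and 1 with 0.81 expected without the first replicates of the APAP and PQ high doses. In the other pairs at least 1 compound had 0 called genes, so these could share none.

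The vehicle groups of 2 days and 1 day differed in 0 genes by limma, with 546 at an unadjusted p under 0.05, and in 11 with array weights and 2 in the fit of only these 10 arrays. PPAR alpha targets, which serve fatty acid oxidation, were nonetheless higher at 2 days as a list, with a median of 0.28 and 22 of 22 members above 0 (camera adjusted p = 6.3e-18; adjusted p = 0.012 with an estimated correlation; fry adjusted p = 0.078). Of these, 0 members were called over all genes and 4 adjusted over the list alone. The falls of this list at 2 days with APAP, INZ and PQ were all measured against these vehicle arrays. A shift of the vehicle arrays cannot be told apart there from an effect of the compounds.

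**Figure D4:**
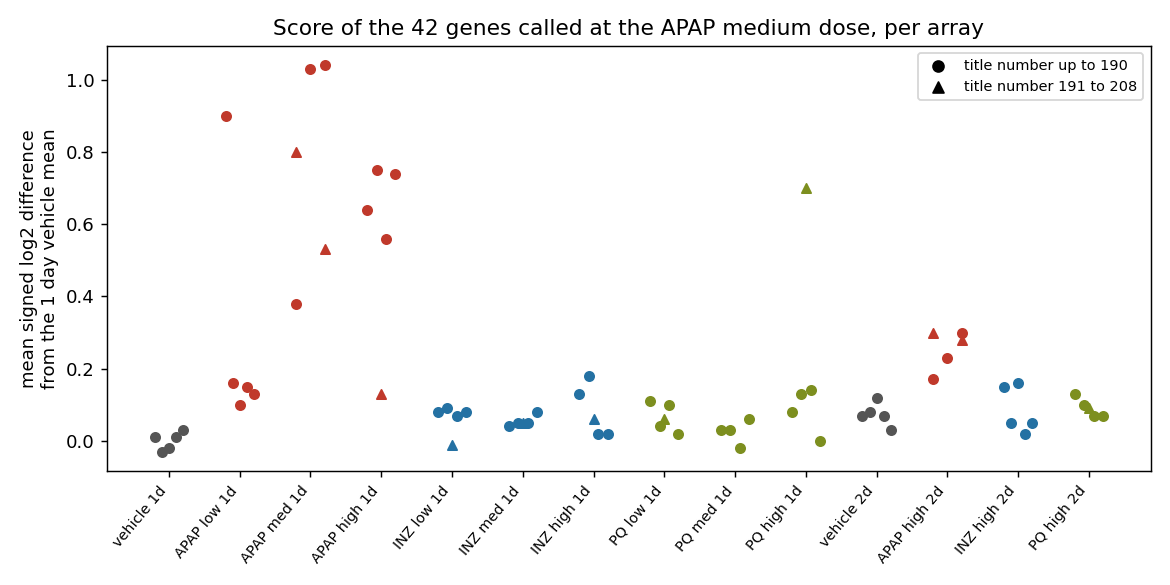
Score of each array, the mean log2 difference from the 1 day vehicle mean over the 42 genes called at the APAP medium dose, by group; circles are arrays with title numbers up to 190 and triangles those with higher numbers. APAP low dose replicate 1 scored 0.9 and PQ high dose replicate 1 scored 0.7, and APAP high dose replicate 1 scored 0.13.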

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

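In this part, only the tests of a paraquat score and the test of the time difference with its splits were chosen before their results were seen, and all other tests of the patterns below, with the measures on which arrays were compared, were chosen after. On 3 measures per array (the first principal component, the score of the 42 genes called at the APAP medium dose, and the array median), 12 of 42 Dixon's tests, 1 for each of the 14 groups on each measure, found an array outside the spread of its group, where chance gives about 1 in 20.

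PQ high dose replicate 1 at 1 day lay with the APAP arrays, at 62.4 on the first principal component against -11.4 to -1.7 in the other 4 arrays of its group and with a score of 0.7 against 0 to 0.14, while APAP high dose replicate 1 at 1 day scored 0.13 against 0.56 to 0.75 in its group. The array batch of title numbers above 190, to which both belong, was argued against as the whole cause, since 0 of 5 other arrays of the batch outside the APAP groups scored above every vehicle array (highest 0.09 against 0.12). An exchange of the labels of these 2 arrays may explain the pattern, and so may individual animals that responded in this way, and these cannot be told apart. On a score of 50 genes chosen from the other PQ high dose arrays, APAP high dose replicate 1 reached 0.46 and PQ high dose replicate 1 reached 0.14, where 30 vehicle, INZ and lower dose APAP arrays had a median of 0.11 and a highest value of 0.47. What keeps it open is that the score placed 0 of the 4 other PQ arrays (0.03 to 0.44) above those 30, and that the 4 other APAP high dose arrays lay between 0.26 and 0.41.

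APAP low dose replicate 1 at 1 day had a first principal component of 59 against -9.3 to -5.5 in its group, a score of 0.9 against 0.1 to 0.16 and a median of 4.549 against 4.405 to 4.435. Of the 10 arrays labelled APAP medium or high dose at 1 day, 1 scored within the range of the other low dose arrays, namely APAP high dose replicate 1 at 0.13, so an exchange of labels with that array may explain both. Against it stand a Cyp2c55 of 6.55 in that array, where the other 4 low dose arrays had 8.07 to 8.28, and a paraquat score of 0.46, where they had -0.10 to 0.13, but these rest on a gene picked with its values in view and on a score that reached 0.47 in arrays without paraquat, and this exchange competes with the one above for the same array. Animals given APAP may also differ in their response: in the low and medium dose groups the mean distance from the group median score was 0.20 in 10 APAP arrays and 0.02 in 19 INZ and PQ arrays (one-sided permutation p = 0.0015), but the genes of the score were called in 1 of these APAP groups and the array in question is included, which fixes a larger distance there, so this test decides nothing. Both explanations stay open.

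Within groups outside APAP, arrays with title numbers above 190 differed from the others in 853 genes, and 1 of 100 assignments of the same numbers of arrays within groups, the real one, called as many (highest other 76), with 5 arrays of the later numbers among 25. An array batch is consistent with these counts, and what the numbers stand for is not known. No vehicle array carried a later number, and with the batch as a term the APAP high dose called 5324 genes at 1 day and 901 at 2 days. No biological explanation was tested for this pattern.

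The other arrays outside the spread of their groups were these. INZ high dose replicate 3 at 1 day had a first principal component of 0.4 against -10.3 to -7.5 and a median of 4.488 against 4.41 to 4.426. PQ high dose replicate 5 at 2 days had a first principal component of -1.7 against -11.5 to -10.2. The score was -0.01 in INZ low dose replicate 1 against 0.07 to 0.09, and 0.08 in INZ medium dose replicate 5 against 0.04 to 0.05. The median was 4.389 in INZ low dose replicate 5 against 4.42 to 4.428, and 4.429 in 2 day vehicle replicate 1 against 4.397 to 4.405.

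The effect of the APAP high dose differed between 2 days and 1 day in 487 genes by a direct test in limma. Of 100 splits of the samples, the real one included, 3 gave at least as many genes, with 695 in the highest other split, a share under 0.05. These splits moved the same APAP high dose arrays between the days, among them replicate 1 at 1 day, which lacks the response of its group. They therefore do not measure chance alone and do not decide this.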

How the results depend on the processing

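The array batch term, the fit of arrays numbered up to 190, the fits without the first replicates of the APAP and PQ high dose groups at 1 day or with their labels exchanged, and leaving out arrays in the list tests were chosen after the data were seen; the other alternatives were planned. Counts in exponent form are rounded to 2 digits. The mean over a gene's probe sets was not run, since each gene had 1. Of the values of named genes in limma, 1802 kept their direction and side of the threshold when 1 array was left out, 253 lost the call, 14 gained one and 1 turned; under the other alternatives 1943 kept theirs, 46 gained the call and the rest lost it. Of the list values 787 kept theirs without 1 array, 61 lost the call and 1 turned, and under the other alternatives 748 kept theirs, 4 turned and the rest lost it. Weaker signals near background limit small changes of dim genes, and with 5 mice per group 1 array can decide a count.

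Leaving out 1 array at a time moved the counts as follows, between the lowest and the highest value. APAP medium dose gave 9 to 1.6e2 genes, without replicates 4 and 2, and APAP high dose at 1 day 2866 to 6721, without replicates 5 and 1. APAP high dose at 2 days gave 2.0e2 to 1141, without replicates 1 and 4. INZ low dose gave 0 to 1, without replicate 2 for the latter, and INZ high dose 0 to 5, without replicates 2 and 1. The APAP trend gave 3168 to 6504, without high dose replicates 5 and 1, and the INZ trend 0 to 2, without high dose replicates 2 and 1. The APAP time difference gave 1.2e2 to 2509, without high dose replicates 3 and 1 at 1 day. APAP against PQ gave 0 to 4449, without PQ replicates 2 and 1, APAP against INZ 2185 to 5848, without APAP replicates 5 and 1, and PQ against INZ 0 to 6, without PQ replicates 1 and 4. Hmox1 at the APAP low dose stood between -0.02 and 0.58, without replicates 1 and 5. The ER chaperones of the PQ high dose at 1 day had camera adjusted p between 1.2e-05 without replicate 3 and 0.90 without replicate 1, where the direction turned. It also turned with array weights (0.97), in arrays numbered up to 190 (0.91), without the first replicates (0.93) and with labels exchanged (0.63).

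The fit of only the groups compared estimates the spread from fewer arrays and from those groups alone. Spreads were unequal, for example SDs for Chil3 of 2.87 at the APAP high dose after 1 day and 0.21 in vehicle. Which of these 2 lowered the counts was not tested. That fit called 2 genes for APAP medium dose, 18 for APAP high dose at 1 day, 28 at 2 days, 0 for INZ high dose at 1 day and 1 at 2 days, and 1 for PQ medium dose. It called 2.0e2 for the APAP trend, 0 for the INZ trend, 11 and 1 for the time differences of APAP and INZ, 2 between vehicles, and 0 for APAP against PQ, APAP against INZ and PQ against INZ. Array weights, lowest for APAP high dose (0.13), PQ high dose (0.142) and APAP low dose (0.167) replicates 1 at 1 day, gave more calls in most comparisons. They called 1, 418 and 8809 genes for the APAP doses and 1584 at 2 days, 15, 4 and 10 for the INZ doses and 1 at 2 days, and 5 for PQ high dose at 1 day. The trends gave 8511 (APAP), 5 (INZ) and 2 (PQ), the time differences 5025 (APAP), 3 (INZ) and 1 (PQ), the vehicles 11, APAP against PQ 7509, APAP against INZ 7914 and PQ against INZ 9.

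With the vehicles of both days, which are more arrays, APAP medium dose gave 332 genes, APAP high dose at 2 days 1402, INZ low dose 4 and INZ high dose at 1 day 11. For the next alternatives the cause was not tested. Without dim genes, APAP medium dose gave 80, the APAP time difference 747 and APAP against PQ 1123. APAP against PQ gave 279 after quantile normalization, 1.8e2 after centring, 2 with the title number as covariate and 401 with the batch term. INZ high dose gave 2 after centring, the APAP time difference 223 with the title number as covariate, and the INZ trend 2 with the batch term. In arrays numbered up to 190, APAP medium dose gave 1733, APAP high dose at 2 days 345, the INZ trend 2, the APAP time difference 3400, APAP against PQ 6210 and PQ against INZ 3. Without the first replicates of the APAP and PQ high doses, APAP medium dose gave 409, the time difference 3052, APAP against PQ 5990 and PQ against INZ 0, and r of APAP and PQ was 0.23. With their labels exchanged these were 404, 3552 and 7117, and APAP against INZ gave 6807. Both were chosen with the arrays in view and are not independent evidence. With the vehicle arrays split, r was 0.17 for APAP and INZ, 0.69 for APAP and PQ and 0.16 for INZ and PQ at 1 day, and 0.28, 0.16 and 0.10 at 2 days.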

Other observations

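The tests of gene lists and of splits in this part were all planned before their results were seen.

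Gene groups without a call by camera at the APAP high dose after 1 day still held single genes called in limma. Over all 17306 probe sets 5207 were called, 2559 higher and 2648 lower. Counts at or below that share are no result about a list. Periportal hepatocyte markers were lower in 6 of 15 members and higher in 2 (camera adjusted p = 0.061), and coagulation and complement genes lower in 6 of 18 (0.084). Cell cycle genes were higher in 7 of 34 members and lower in 2 (0.34), with Top2a at 0.18 (adjusted p 0.73). Glucocorticoid targets were higher in 5 of 14 members and lower in 2 (0.14), antioxidant enzymes higher in 5 of 19 and lower in 5 (0.34), PPAR alpha targets higher in 4 of 22 and lower in 5 (0.72), and gluconeogenesis and fasting genes higher in 3 of 14 and lower in 3 (0.69). Endothelial markers were higher in 5 of 18 members and lower in 4 (0.39), general hepatocyte genes higher in 2 of 18 and lower in 4 (0.40), and heme and iron genes higher in 2 of 18 and lower in 3 (0.56). Interferon response genes were higher in 2 of 21 members and lower in 2 (0.56), Kupffer cell markers higher in 1 of 13 and lower in 1 (0.56), and cholangiocyte markers higher in 1 of 12 and lower in 1 (0.84). Pancreatic acinar genes were lower in 2 of 10 members (0.089), female-biased liver genes in 1 of 10 (0.25) and adipose genes in 1 of 7 (0.40). B cell markers (8 measured) and T and NK cell markers (16 measured) held 0 genes called by limma, with camera adjusted p of 0.56 and 0.64.

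Splits of the samples into groups of the same sizes, 100 for each comparison with the real one included, gave these counts. As many genes as the real split were called by 1 split, the real one, for APAP medium dose (42 genes, highest other 6) and APAP high dose at 1 day (5207, 5180). The same held for APAP high dose at 2 days (776, 581), INZ high dose at 1 day (4, 1) and PQ against INZ (5, 2). For the APAP trend 2 splits did so (5076, 5101). All these shares were under 0.05, each judged alone with no adjustment over comparisons. At that share chance was excluded for APAP medium dose, APAP high dose at 2 days, INZ high dose at 1 day and PQ against INZ. The split with 5180 genes moved APAP high dose replicate 1 and 1 day vehicle replicate 2, which points to the structure of the arrays described for APAP high dose replicate 1. It came close to 5207, and for the APAP trend another split called more genes than the real one. The splits therefore do not measure chance alone for these 2 comparisons and do not decide them. For the INZ trend 8 splits gave as many (1; 7), for APAP against INZ 5 (4279; 5122) and for APAP against PQ 17 (67; 7117), so chance was not excluded there. The split with 7117 genes exchanged the first replicates of PQ and APAP, and the one with 5122 moved APAP high dose replicate 1 and INZ high dose replicate 3; such counts point to a structure of the samples. For the comparisons with 0 called genes, 100 of 100 splits gave as many.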
